A study of Homo sapiens with 12 samples.

How the data were processed

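RNA was sequenced from HCT116 cells in 4 groups of 3 biological replicates, and each library's group and replicate number came from its title in the labels. Per the labels' protocols, RNA was isolated with TRIzol and made into libraries with the TruSeq RNA v2 kit, which does not mark the strand. The deposited table holds raw whole-number counts of reads per gene for 23710 gene symbols in 12 libraries. Per the submitters' processing notes, Trimmomatic 0.39, TopHat2 2.0.6 and HTSeq were used with the genome build hg19. The gene annotation, the strand setting, the handling of reads with several matches and any filter are not given in the sources used here. Without the strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads of near-identical genes and pseudogenes may be lost or split. All values of the table named a gene, and 3118 genes had 0 counts in all libraries.

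Totals, from 36624548 to 47727883 counts per library, make 1 count worth 0.0209 to 0.0269 CPM, and a level of 3 counts worth 0.0628 to 0.0806 CPM. These cover counting error only. For each replicate pair, counts were compared with a chi-square over genes. Its value per degree of freedom lay between 7.506 and 30.66, so no pair agreed within sampling noise and none was merged.

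Computations ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Counts were tested as deposited with edgeR's quasi-likelihood F-test with robust dispersion estimates and TMM scaling factors (0.9588 to 1.033). Genes were kept by filterByExpr, with a minimum count of 10 and a minimum total of 15, which left 16115. All 12 libraries entered 1 fit with 1 coefficient per group, so that the 4 groups shared 1 estimate of the spread with 8 residual degrees of freedom. The comparisons were DAZAP2 siRNA against control siRNA in DMSO and under 5-FU, 5-FU against DMSO with each siRNA, and the interaction. P-values were adjusted by Benjamini-Hochberg within a comparison with a threshold of 0.05, and every adjusted p of a gene is from this edgeR test unless another tool is named. Levels are TMM-scaled CPM as mean ± SD (n = 3), folds are fitted, and SE is the standard error of a log2 fold change.

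Gene lists, 35 in all, were tested with camera from limma on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, for lists with at least 5 tested members. Camera was run again with an estimated correlation. Adjustment was over the lists within a comparison, and member counts are given over all genes and adjusted over the list alone. The tests, the comparisons, the gene lists, the rule for named genes and all alternatives except those said to be added later were fixed before the data were examined. By that rule the text could name the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the 3 values of the groups. Chance alone gives no overlap for 10% of genes with 3 against 3. The rule also named DAZAP2, HIPK2 and SIAH1, and up to 4 members of a list with the smallest p. Of those list members with a call, the text names those whose call held without each library, and counts the others. Some members without a call are named too, with their adjusted p. Some genes that the rule takes are not reported here. Members given without a value to complete a count of 5 or fewer were chosen after their values were seen, and their calls were not followed with libraries left out.

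Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means, with all 3 pairs above 0.1 taken as paired. The labels give the numbers and do not say that they mark a shared day. The numbers paired siDAZAP2_5-FU with siCTRL_5-FU (0.177, 0.286 and 0.378) and with siDAZAP2_DMSO (0.102, 0.276 and 0.241). The replicate number as a block was an alternative fit. Other alternatives were DESeq2's test, DESeq2's size factors, no filter on low counts, a fit of only the groups compared, an estimated correlation and leaving out each library. Added after the data were seen were fits without both DMSO libraries numbered 3, counts over genes without siRNA seed sites, and leaving out libraries for the correlations of fold changes.

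Sites where an siRNA could bind 3′ UTRs through its seed were sought with 7-mers, since the siRNA sequences are not given in the sources used here. GENCODE release 29 (GRCh38) supplied gene positions, spans, 3′ UTRs and transcripts. It is not the build of the counts, and was joined by gene symbol: 22336 of 23710 symbols matched (94.2%), 1079 of them through 1 older symbol. Among 11573 genes with a 3′ UTR of at least 50 bases and a mean log2 CPM of at least 1, each of 16350 7-mers found in at least 30 genes was regressed against the log2 fold change, limited to ±1.5, with 3′ UTR length in 20 bins and GC content held. Its z was compared with the extremes over 100 permutations of genes within length bins. A gene counted as free of seed sites when its annotated 3′ UTR held neither the leading 7-mer nor its last 6 bases.

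The test of genes and the test of lists were tested on simulated counts made from the real means and library sizes with 200 changed genes. Camera with the preset correlation called a planted list of 30 genes changed 1.25-fold in every comparison, and 0 of 20 random lists. Counts were drawn independently for each gene. The simulation therefore cannot tell whether the preset correlation gives false list calls where genes are correlated. The 7-mer regression was tested on permuted fold changes with a planted 7-mer, and the other steps were not tested on simulated data. For DAZAP2 siRNA in DMSO (16023 genes) the gene test recovered 67.2% of genes changed 1.5-fold, 83.3% of those changed 2-fold and 95.5% of those changed 4-fold. For DAZAP2 siRNA under 5-FU (16010 genes) it recovered 61.2%, 81.8% and 100%. For the interaction it recovered 44.8%, 72.7% and 95.4%, so a difference of 1.5-fold between responses would be missed in most genes.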

Results

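RNA levels were measured by sequencing in HCT116, a human colorectal carcinoma line that carries wild-type p53. Cells were transfected with a small interfering RNA (siRNA) against DAZAP2 or with a control siRNA. They then received either the solvent DMSO or 50 µM 5-fluorouracil (5-FU) for 24 h. 5-FU is a pyrimidine analogue whose metabolites block thymidylate synthase and enter RNA and DNA. DAZAP2 encodes a small proline-rich adaptor protein. The series set out to find genes that depend on DAZAP2 in undamaged cells and after DNA damage. The 4 groups held 3 biological replicates each, 12 libraries in all, and are called siCTRL_DMSO, siDAZAP2_DMSO, siCTRL_5-FU and siDAZAP2_5-FU. Total counts for replicates 1, 2 and 3 were 44199402, 40571871 and 36624548 in siCTRL_DMSO and 47727883, 44530757 and 46028513 in siDAZAP2_DMSO. They were 40195675, 45249335 and 46244918 in siCTRL_5-FU and 39083218, 40926795 and 44587491 in siDAZAP2_5-FU. Between 18221 and 18936 genes had at least 1 count in a library, and 16115 genes entered the tests. The first principal component of log2 CPM, read counts scaled to library size, held 68.6% of the variance and parted the drug groups from the DMSO groups. The second held 8.52% and parted the siRNAs.

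DAZAP2 was measured first, in every library, because it was the gene targeted. It lies on chromosome 12 from 51238292 to 51271362 (GRCh38). Its level was 191 ± 25 CPM (SD, n = 3) in siCTRL_DMSO and 23.1 ± 9.1 CPM in siDAZAP2_DMSO. Under 5-FU it was 164 ± 11 CPM with the control siRNA and 20.9 ± 7.4 CPM with DAZAP2 siRNA. DAZAP2 siRNA lowered the transcript 8.26-fold in DMSO (log2 fold change −3.05, SE 0.29, adjusted p = 0.00029) and 7.82-fold in 5-FU (−2.97, SE 0.29, adjusted p = 0.00043). The 6 libraries with DAZAP2 siRNA lay between 15 and 33.04 CPM and the 6 with control siRNA between 151.5 and 214 CPM. The log2 fold change of DAZAP2 with 5-FU was −0.22 with control siRNA (adjusted p = 0.543) and −0.14 with DAZAP2 siRNA (adjusted p = 0.721). The value with DAZAP2 siRNA was 0.21 without siDAZAP2_DMSO replicate 2 and 0.04 without siDAZAP2_5-FU replicate 1. HIPK2 encodes a kinase that phosphorylates p53 after DNA damage, and SIAH1 a ubiquitin ligase that acts on HIPK2. With DAZAP2 siRNA their log2 fold changes in DMSO were 0.10 for HIPK2 (adjusted p = 0.554) and −0.13 for SIAH1 (0.625). In 5-FU they were 0.20 for HIPK2 (adjusted p = 0.232) and 0.07 for SIAH1 (0.869). Without siCTRL_DMSO replicate 2 the SIAH1 value in DMSO was 0.0029. In 5-FU it was −0.0096 without siCTRL_5-FU replicate 3 and −0.06 without siDAZAP2_5-FU replicate 1.

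**Figure D1:**
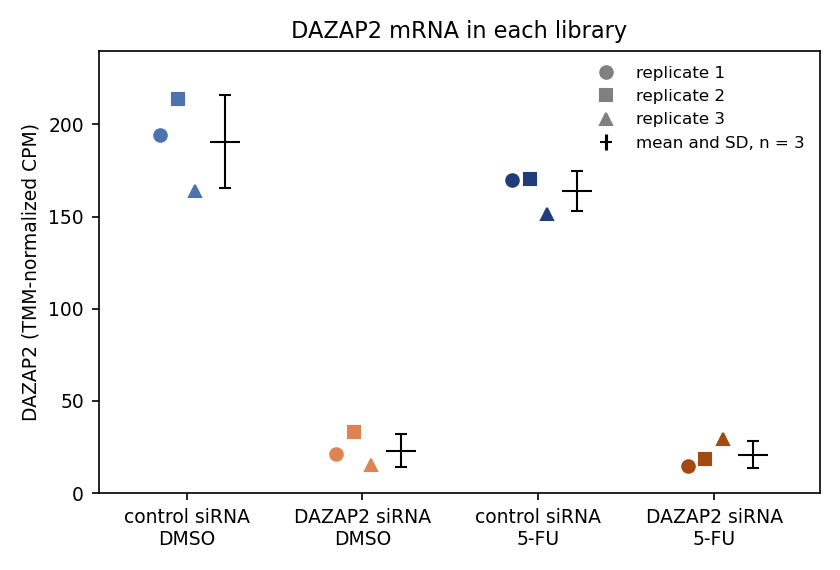
DAZAP2 level in CPM (y axis, from 0) in each of the 12 libraries (points) by group (x axis), with the group mean and SD (n = 3). The 6 libraries with DAZAP2 siRNA lie at or below 33.04 CPM, and the 6 with control siRNA lie at or above 151.5 CPM.

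The effect of DAZAP2 siRNA without drug was the difference between siDAZAP2_DMSO and siCTRL_DMSO. C14orf1, a protein of sterol synthesis, rose 3.43-fold, from 13.2 ± 2.6 to 45.3 ± 5.7 CPM (log2 fold change 1.78, SE 0.14, adjusted p = 3.73e-07). The cell-surface proteoglycan GPC4 rose 2.79-fold, from 10.2 ± 1.4 to 28.5 ± 0.79 CPM (1.48, SE 0.12, adjusted p = 3.73e-07). The actin-binding protein TAGLN fell 3.32-fold, from 15.6 ± 5 to 4.68 ± 0.62 CPM (log2 fold change −1.73, SE 0.21, adjusted p = 8.69e-05), and the myosin light chain MYL9 fell 2.2-fold, from 102 ± 12 to 46.3 ± 5.2 CPM. The keratins KRT80 (log2 fold change −1.62, SE 0.14) and KRT7 (−1.60, SE 0.23), the carboxypeptidase CPA4 (2.83-fold lower, SE of the log2 fold change 0.11) and the latent TGF-beta binding protein LTBP2 (−1.10) also fell. Further genes that rose were TIMM17B (log2 fold change 1.23), KANK2 (1.13), C4orf46 (1.10), CDC42SE2 (1.02), CYB5R3 (0.93) and NFIX (0.91). Among the genes that rose, C14orf1, GPC4, KANK2 and C4orf46 carried the 7-mer TGTACGT in an annotated 3′ UTR. CYB5R3 and NFIX carried its last 6 bases, and TIMM17B and CDC42SE2 carried neither. Those 6 bases stood in 5.78% of genes not called in DMSO. TGTACGT is the 7-mer most strongly associated with higher levels under DAZAP2 siRNA, and CCGCATT is the one most strongly associated with lower levels. In all, 944 of 16115 genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 481 higher and 463 lower, and 55 of them changed at least 2-fold. The count was 438 without siCTRL_DMSO replicate 3, 522 without siDAZAP2_DMSO replicate 1, 426 without replicate 2 and 547 without replicate 3 of that group. It was 226 without both DMSO libraries numbered 3, 481 when the 6 DMSO libraries alone were fitted and 1429 with DESeq2.

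Of 21 mesenchymal and extracellular matrix genes, 8 fell with DAZAP2 siRNA in DMSO and 13 did not pass the test (9 fell adjusted over the list alone). Among them were the matrix protein THBS1 (log2 fold change −0.55, SE 0.09, adjusted p = 0.00146) and CYR61 (−0.62, SE 0.11). The list was lower as a set (camera adjusted p = 5.25e-06, but adjusted p = 0.728 with an estimated correlation), with a median of −0.37. Of 36 genes of DNA replication, 4 rose (13 adjusted over the list alone), among them the cyclin CCNE2 (1.85-fold, 0.89, SE 0.11, adjusted p = 7.01e-05) and E2F2 (0.50, SE 0.08). The other 2 were POLA1 and RRM2. Of 34 genes of G2 and mitosis, 3 rose and 1 fell (9 and 1 adjusted over the list alone). Those that rose were BIRC5, CDK1 and PRC1. The spindle midzone protein PRC1 rose 1.7-fold (0.76, SE 0.09, adjusted p = 7.46e-05). PRC1 carried the last 6 bases of TGTACGT in its 3′ UTR. FOXM1, a transcription factor that drives mitotic genes, fell 1.41-fold, from 195 ± 4.2 to 139 ± 8.5 CPM (−0.49, SE 0.09, adjusted p = 0.00279). Both lists were higher as sets, with camera adjusted p = 7.42e-10 for replication and 0.000178 for mitosis, and adjusted p = 0.728 for each with an estimated correlation.

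Of 98 p53 target genes, 7 rose and 7 fell in DMSO (14 and 16 adjusted over the list alone), and the list as a set did not differ from other genes (camera adjusted p = 0.919, median −0.014). The sign of the set test turned from lower to higher without siCTRL_DMSO replicate 2 (adjusted p = 0.838), siDAZAP2_DMSO replicate 1 (0.935) or siDAZAP2_DMSO replicate 3 (0.661). The ubiquitin ligase MDM2, which degrades p53, fell 1.4-fold from 298.8 ± 46.5 to 212.7 ± 11.7 CPM (log2 fold change −0.49, SE 0.09, adjusted p = 0.00231). PLK2 (−0.47, SE 0.08) fell, and SAC3D1 (0.74, SE 0.12), STEAP3 (0.59, SE 0.11) and GPX1 (0.53, SE 0.10) rose. STEAP3 and GPX1 carried the last 6 bases of TGTACGT in a 3′ UTR. Of 22 genes of pyrimidine and 5-FU metabolism, 2 rose and 2 fell (6 and 3 adjusted over the list alone). Cytidine deaminase, CDA, fell 1.58-fold (−0.66, SE 0.12, adjusted p = 0.00276), and UMPS, which converts 5-FU to its nucleotide, fell by 0.40 on the log2 scale (SE 0.08). The genes that rose were RRM2 and SAMHD1. UMPS carried CCGCATT in its 3′ UTR. The list as a set had camera adjusted p = 0.0757, and 0.0369 without siDAZAP2_DMSO replicate 3 (adjusted p = 0.728 with an estimated correlation).

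Other sets were higher with DAZAP2 siRNA in DMSO, and each lost its call without at least 1 single library. Of 18 genes of the unfolded protein response, 5 rose and 13 did not pass the test (5 rose adjusted over the list alone). HERPUD1 rose by 0.37 (log2, SE 0.08) and carried TGTACGT in its 3′ UTR, and the others were CRELD2, PDIA4, SDF2L1 and SEC61B. The set had camera adjusted p = 0.0132 (adjusted p = 0.728 with an estimated correlation), which was 0.232 without siCTRL_DMSO replicate 3 and 0.0584 without siDAZAP2_DMSO replicate 1. Of 27 nuclear genes of oxidative phosphorylation, 3 rose, SDHA, UQCRC1 and UQCRFS1 (7 adjusted over the list alone). That set had camera adjusted p = 0.00218 (adjusted p = 0.728 with an estimated correlation), which was 0.124 without siCTRL_DMSO replicate 3 and 0.0827 without siDAZAP2_DMSO replicate 2. The 30 ribosomal protein genes did not pass the test singly, over all genes or adjusted over the list alone, while the set had camera adjusted p = 0.00324 with a median of 0.087, and 0.219 without siDAZAP2_DMSO replicate 2. It had adjusted p = 0.728 with an estimated correlation. Genes spanning up to 8.91 kb had a median of 0.0652 in this comparison, and those from 91.7 kb had −0.0642. The list tests did not hold gene span, spliced length or GC content, so a part of these shifts in such a trend was not tested.

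The effect of DAZAP2 siRNA under 5-FU was the difference between siDAZAP2_5-FU and siCTRL_5-FU. C14orf1 rose 3.79-fold, from 12.4 ± 2.3 to 46.8 ± 2.9 CPM (log2 fold change 1.92, SE 0.14, adjusted p = 3.15e-07), and GPC4 rose 2.66-fold (1.41, SE 0.11, adjusted p = 1.21e-06). The hair keratin KRT81 fell 4.91-fold, from 5.28 ± 1.7 to 1.07 ± 0.18 CPM (−2.29, SE 0.28, adjusted p = 0.000101), and TAGLN fell 3.27-fold, from 30.5 ± 7.4 to 9.33 ± 1 CPM (−1.71, SE 0.20, adjusted p = 6.92e-05). KRT7 (log2 fold change −1.21, SE 0.21), KRT80 (−1.17, SE 0.13), EFR3B (−1.16), the pore-forming protein PRF1 (−1.06, SE 0.14) and MYL9 (−1.01, SE 0.11) also fell. Reads of KRT81 can be shared with near-identical keratin genes, so its own level is uncertain. C4orf46 (1.18), TIMM17B (1.06), CDC42SE2 (1.06), KANK2 (1.03), the ubiquitin ligase RNF11 (0.98, SE 0.10) and AMMECR1 (0.94) rose. C14orf1, GPC4, KANK2 and C4orf46 carried TGTACGT, as above, and RNF11 and AMMECR1 carried its last 6 bases. In all, 710 genes changed, 393 higher and 317 lower, and 44 changed at least 2-fold. The count was 269 without siCTRL_5-FU replicate 2, 352 without siCTRL_5-FU replicate 3, 341 without siDAZAP2_5-FU replicate 1 and 417 without siDAZAP2_5-FU replicate 2. It was 1067 when the 6 libraries with 5-FU alone were fitted.

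Of 34 genes of G2 and mitosis, 15 rose and 1 fell with DAZAP2 siRNA under 5-FU (27 and 2 adjusted over the list alone). PRC1, which carried the last 6 bases of TGTACGT, rose 1.92-fold, from 73.4 ± 8.2 to 140 ± 5.7 CPM (log2 fold change 0.94, SE 0.09, adjusted p = 1.69e-05). The mitotic kinase CDK1 rose 1.47-fold, from 135 ± 14 to 198 ± 13 CPM (0.55, SE 0.09, adjusted p = 0.00184), and the spindle checkpoint kinase BUB1 rose 1.35-fold (0.43, SE 0.08, adjusted p = 0.0035). FOXM1 was the member that fell, 1.48-fold, from 171 ± 12 to 115 ± 17 CPM (−0.57, SE 0.09, adjusted p = 0.00107). The set had camera adjusted p = 2.49e-14 and a median of 0.30, but adjusted p = 0.601 with an estimated correlation. Of 36 replication genes, 8 rose (16 adjusted over the list alone), with camera adjusted p = 5.83e-12 (adjusted p = 0.601 with an estimated correlation). CCNE2 rose 1.89-fold (0.92, SE 0.10), the DNA polymerase subunit POLA1 rose 1.58-fold (0.66, SE 0.10) and E2F2 rose by 0.48 (SE 0.08). Of 21 mesenchymal and matrix genes, 5 fell (7 adjusted over the list alone), among them THBS1 (−0.63, SE 0.09) and TAGLN, with camera adjusted p = 2.45e-05 (adjusted p = 0.601 with an estimated correlation).

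**Figure D2:**
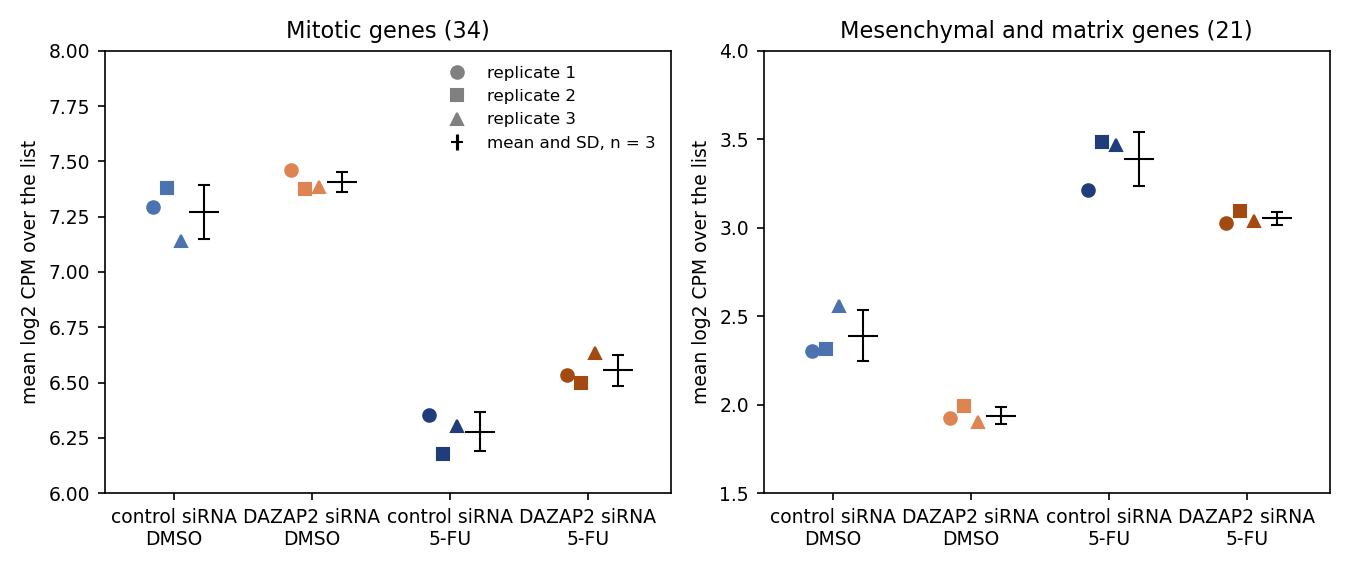
Mean log2 CPM (y axis) of 34 genes of G2 and mitosis and of 21 mesenchymal and matrix genes in each of the 12 libraries (points), by group. Under 5-FU the mitotic mean was 6.353, 6.179 and 6.304 with control siRNA and 6.536, 6.496 and 6.634 with DAZAP2 siRNA, and in DMSO it was 7.293, 7.379 and 7.14 against 7.459, 7.373 and 7.386, which overlap. In DMSO the matrix mean was 2.301, 2.313 and 2.555 against 1.922, 1.991 and 1.9.

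Of 98 p53 targets, 9 rose and 1 fell with DAZAP2 siRNA under 5-FU (10 and 1 adjusted over the list alone). TP53INP1, a p53-induced nuclear protein, rose 1.41-fold, from 144 ± 7.5 to 202 ± 15 CPM (log2 fold change 0.50, SE 0.10, adjusted p = 0.00458), and SAC3D1 rose by 0.66 (SE 0.12). The target that fell was NOTCH1. For the cell cycle inhibitor CDKN1A the value was 0.11 (adjusted p = 0.604), and for MDM2 it was −0.26 (adjusted p = 0.0994). The set had camera adjusted p = 0.0333 with a median of 0.051, and adjusted p = 0.886 with an estimated correlation. Its camera adjusted p was 0.0785 without siCTRL_5-FU replicate 1, 0.168 without siCTRL_5-FU replicate 3 and 0.17 without siDAZAP2_5-FU replicate 2. Of 22 genes of pyrimidine and 5-FU metabolism, 2 rose and 3 fell (6 and 4 adjusted over the list alone), with camera adjusted p = 0.391. Deoxycytidine kinase, DCK, rose by 0.54 (SE 0.10, adjusted p = 0.00267), and UMPS fell by 0.42 (adjusted p = 0.00373). The others were RRM1, which rose, and CDA and TYMP, which fell.

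In 4 further lists the sets passed under 5-FU while most members did not pass singly. Of 18 unfolded protein response genes 1 rose, HERPUD1 (2 adjusted over the list alone), with camera adjusted p = 0.00537 (adjusted p = 0.886 with an estimated correlation). Of 18 DNA repair genes 1 rose, RAD54L (3 adjusted over the list alone), with 0.00674 (adjusted p = 0.886 with an estimated correlation), which was 0.093 without siCTRL_5-FU replicate 2 and 0.202 without siDAZAP2_5-FU replicate 3. Of 27 oxidative phosphorylation genes 1 fell, NDUFA4, although the set was higher (1 higher and 1 lower adjusted over the list alone), with 0.00571 (adjusted p = 0.886 with an estimated correlation), which was 0.14 without siCTRL_5-FU replicate 3. Of 18 epithelial and intestinal genes 1 fell, MUC13, and the set was lower (1 higher and 2 lower adjusted over the list alone), with 0.028 (adjusted p = 0.886 with an estimated correlation), which was 0.176 without siCTRL_5-FU replicate 2 and 0.178 without siDAZAP2_5-FU replicate 3.

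The effects of DAZAP2 siRNA in DMSO and under 5-FU were set side by side. Changes in the same direction in both treatments were called for 377 genes, of which 219 were higher and 158 lower, among them C14orf1, GPC4, TAGLN, KRT7, KRT80, MYL9 and PRC1. Independent lists would share 11.7 higher and 9.11 lower genes, and the comparisons had no library in common. Across 16115 genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.505 and Spearman's rho of 0.495. The jackknife SE of r over libraries was 0.0887, and r was 0.0857 when genes with low counts were kept. Of the 944 genes called in DMSO, 97.25% had the same sign under 5-FU, and of the 710 called under 5-FU, 99.3% had the same sign in DMSO.

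**Figure D3:**
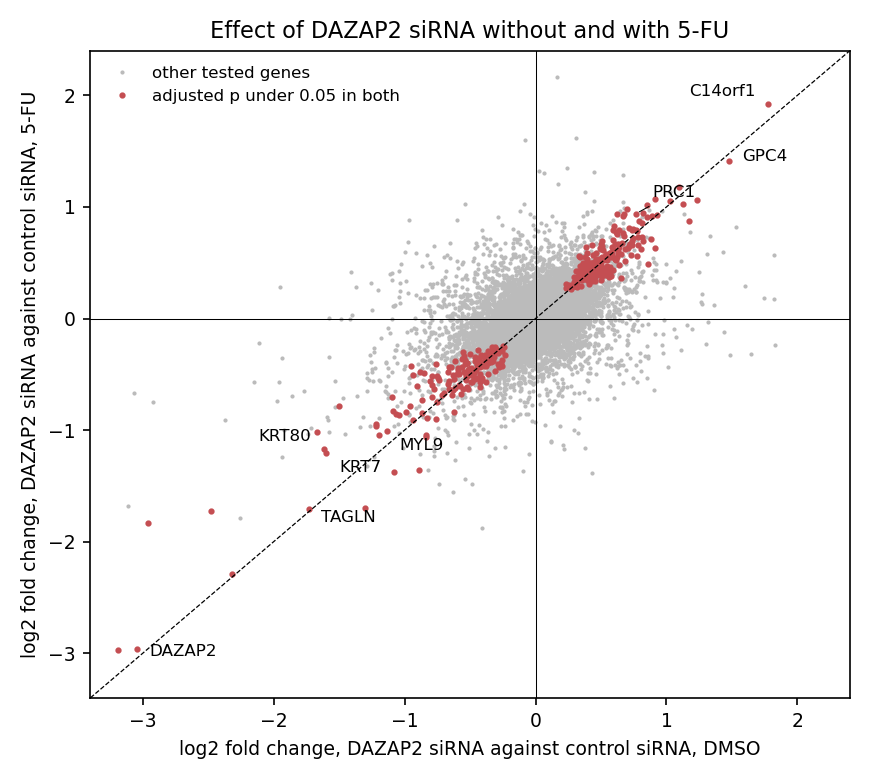
Log2 fold change with DAZAP2 siRNA in DMSO (x axis) and under 5-FU (y axis) for each tested gene (points), with the 377 genes called in both in red and 4 genes outside the axes. C14orf1 lies at 1.78 and 1.92, DAZAP2 at −3.05 and −2.97, and TAGLN at −1.73 and −1.71.

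The response to 5-FU in cells with control siRNA was the difference between siCTRL_5-FU and siCTRL_DMSO. The adhesion molecule CEACAM1 rose 73.7-fold, from 0.454 ± 0.16 to 33.4 ± 6.6 CPM (log2 fold change 6.20, SE 0.23, adjusted p = 1.52e-13), and the secreted stress cytokine GDF15 rose 16.5-fold, from 69.8 ± 11 to 1152 ± 137 CPM (4.04, SE 0.16, adjusted p = 8.81e-13). The epidermal proteins FLG (22.8-fold, 4.51) and HRNR (4.11), the receptor SORCS2 (4.48), the adhesion molecule PVRL4 (17-fold, 4.09, SE 0.12), the platelet-activating factor receptor PTAFR (15-fold, 3.91) and MYH16 (3.97), a pseudogene in humans, also rose. The mitotic kinase PLK1 fell 4.39-fold, from 227 ± 21 to 51.7 ± 2.6 CPM (−2.13, SE 0.08, adjusted p = 1.2e-13). The helicase PIF1 (6.3-fold lower, −2.66, SE 0.16), the ribosomal protein-like RPL22L1 (5.01-fold, −2.33, SE 0.09), the hyaluronan receptor HMMR (4.19-fold, −2.07) and LRRCC1 (−1.85) also fell. Reads of CEACAM1, RPL22L1 and HRNR can be shared with related genes or pseudogenes, so their own levels are uncertain. In all, 7527 of 16115 genes changed, 3853 higher and 3674 lower, and 1314 changed at least 2-fold, 1019 of them higher. HIPK2 fell from 133 ± 4.5 to 101 ± 7 CPM (−0.41, SE 0.09, adjusted p = 0.000703). SIAH1 fell by 0.40 (SE 0.13, adjusted p = 0.02), but its adjusted p was 0.117 without siCTRL_DMSO replicate 2 and 0.0908 without siCTRL_5-FU replicate 3.

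Nearly all p53 targets rose with 5-FU: of 98 tested, 92 rose and 3 fell (92 and 3 adjusted over the list alone), with a median log2 fold change of 1.30. The cell cycle inhibitor CDKN1A rose 9.49-fold, from 213.2 ± 14.7 to 2023 ± 135 CPM (3.25, SE 0.10, adjusted p = 1.31e-14), and MDM2 rose 5.02-fold, from 298.8 ± 46.5 to 1499 ± 22.9 CPM (2.33, SE 0.09, adjusted p = 2.51e-13). TP53I3, an oxidoreductase, rose 12.4-fold, from 11.6 ± 1.2 to 143 ± 4.2 CPM (3.63, SE 0.11, adjusted p = 8.38e-15). The death receptor FAS rose 6.15-fold (2.62, SE 0.11), the 14-3-3 protein SFN 6.91-fold (2.79, SE 0.09), the damage recognition protein DDB2 3.22-fold (1.69, SE 0.08), the phosphatase PPM1D by 1.99 (SE 0.10) and FDXR by 1.92 (SE 0.11). The targets that fell were KITLG, MDM4 and WRAP53, which were singled out after their values were seen. By function, 13 of 13 targets of cell cycle arrest rose, as did 16 of 17 of apoptosis, 19 of 21 of repair and metabolism, 39 of 40 other targets and 7 of 9 targets that feed back on p53, with the same counts adjusted over the list alone. The whole list had camera adjusted p = 7.77e-38, and adjusted p = 0.00951 with an estimated correlation. The feedback targets had adjusted p = 0.00104, and 0.206 with an estimated correlation.

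Of 34 genes of G2 and mitosis, 32 fell with 5-FU (33 adjusted over the list alone), with a median of −0.93. The Aurora kinase AURKA fell 3.04-fold (log2 fold change −1.61, SE 0.07) and CDC20, an activator of the anaphase-promoting complex, fell 2.85-fold (−1.51, SE 0.07). Of 36 replication genes, 24 fell and 5 rose (25 and 5 adjusted over the list alone). The helicase subunit MCM6 fell 2.31-fold, from 253 ± 17 to 109 ± 3.3 CPM (−1.21, SE 0.07, adjusted p = 9.03e-11), and MCM7 fell by 0.98. The replication genes that rose were CCNE1, CCNE2, PCNA, RRM1 and RRM2, of which PCNA is also a p53 target. The camera adjusted p was 2.55e-19 for mitosis and 5.77e-06 for replication, and with an estimated correlation the adjusted p was 0.135 and 0.31. Of 30 genes of RNA processing, 21 fell and 2 rose (21 and 2 adjusted over the list alone), among them SRSF2 (−0.81, SE 0.07) and HNRNPU (−0.70, SE 0.07), and the kinases CLK1 and CLK4 rose. Of 13 heat shock genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), and the chaperone HSPA8 fell 2.39-fold (−1.26, SE 0.07) and HSPA4L was the gene that rose. Reads of HSPA8 can be shared with pseudogenes. These sets had camera adjusted p = 4.15e-06 and 0.000501, and adjusted p = 0.273 for each with an estimated correlation.

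Of 26 genes of ribosome biogenesis, 14 fell and 3 rose (15 and 3 adjusted over the list alone), among them the RNA polymerase I factor UBTF (log2 fold change −0.78), while BYSL, NOP2 and RRP12 rose, with camera adjusted p = 0.00353 (adjusted p = 0.449 with an estimated correlation). Of 30 ribosomal protein genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone), with camera adjusted p = 0.00564 (adjusted p = 0.594 with an estimated correlation). RPL10A fell by 1.61 (SE 0.07) and RPL3 fell by 1.01 (SE 0.07), and reads of both can be shared with pseudogenes, while RPS19 rose. Of 22 genes of cholesterol synthesis, 9 fell and 2 rose (9 and 2 adjusted over the list alone), with LSS at −0.83 (SE 0.10) and HMGCS1 at −0.73 (SE 0.10). That set had camera adjusted p = 0.0362 (adjusted p = 0.594 with an estimated correlation), which was 0.14 without siCTRL_DMSO replicate 2 and 0.0761 without siCTRL_5-FU replicate 1. Of 19 genes for HIPK2 and partners of it or DAZAP2, 9 fell and 2 rose (9 and 3 adjusted over the list alone). The risen ones were PML and WSB1, and the list had camera adjusted p = 0.0227 and adjusted p = 0.135 with an estimated correlation.

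Among genes of the integrated stress response, the mitochondrial enzyme PCK2 fell 6.57-fold, from 37 ± 16 to 5.62 ± 0.28 CPM (log2 fold change −2.71, SE 0.39, adjusted p = 0.000253). Asparagine synthetase, ASNS, fell 4.26-fold, from 249 ± 81 to 58.5 ± 3.2 CPM (−2.09, SE 0.30, adjusted p = 0.00026), and CHAC1 fell by 2.05 (SE 0.45, adjusted p = 0.00359). ASNS stood at 342.5 and 409.3 CPM in the DMSO libraries numbered 3, against 184.2 to 215.1 CPM in the other 4 DMSO libraries. PCK2 stood at 55.09 and 69.86 CPM in the same libraries, against 24.89 to 36.5 CPM. Of 24 genes of this response, 13 fell and 4 rose (14 and 4 adjusted over the list alone). The regulator ATF4 fell by 0.74 (SE 0.08), while ATF3, which is also a p53 target, rose 7.44-fold (2.90, SE 0.15), and CEBPB, SESN2 and VLDLR rose too. The set had camera adjusted p = 0.0114 (adjusted p = 0.594 with an estimated correlation), and 0.0528 without siCTRL_DMSO replicate 3. Without both DMSO libraries numbered 3, the response to 5-FU comprised 7114 genes.

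Of 17 NF-κB and inflammatory genes, 11 rose and 1 fell with 5-FU (11 and 1 adjusted over the list alone), including the apoptosis inhibitor BIRC3 (4.08-fold, log2 fold change 2.03, SE 0.13), TNFAIP3 (1.78, SE 0.11) and ICAM1 (1.68, SE 0.15), while NFKB1 fell. The set had camera adjusted p = 0.000414, and adjusted p = 0.0345 with an estimated correlation. Of 25 growth factor and MAPK genes, 18 rose and 2 fell (18 and 2 adjusted over the list alone), including the EGF receptor ligands HBEGF (3.9-fold, 1.97, SE 0.10) and AREG (1.42, SE 0.08) and the phosphatase DUSP5 (1.68, SE 0.10), while ETV5 and SPRY2 fell, with camera adjusted p = 3e-06 and adjusted p = 0.194 with an estimated correlation. Of 21 mesenchymal and matrix genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone), including SNAI2 (3.88, SE 0.22), CYR61 (2.48, SE 0.11), THBS1 (1.81) and the protease PLAU (2.08, SE 0.09), while ITGA5 and VIM fell. Of 18 epithelial and intestinal genes, 13 rose (13 adjusted over the list alone), including the mucin MUC13 (3.50, SE 0.21). These sets had camera adjusted p = 0.000414 and 2.86e-05, and adjusted p = 0.206 and 0.214 with an estimated correlation.

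Of 27 genes of autophagy and the lysosome, 17 rose and 1 fell in cells with control siRNA (17 and 1 adjusted over the list alone), including the protease CTSD (log2 fold change 1.02, SE 0.12) and GABARAPL1 (0.65), while BECN1 fell. Of 30 interferon-induced genes, 14 rose and 4 fell (14 and 4 adjusted over the list alone). The camera adjusted p was 0.00181 for autophagy and 0.0146 for interferon, and with an estimated correlation the adjusted p was 0.273 and 0.194. CDA rose by 0.74, and DUT, which hydrolyses dUTP, fell by 0.78. Markers of other cell types were sparse: 4 of 12 fibroblast markers, 6 of 12 blood cell markers and 5 of 12 neural or liver markers had enough counts to be tested. With 5-FU, 2 of the 4 fibroblast markers, ACTA2 and COL1A1, rose (2 adjusted over the list alone), 2 of the 6 blood cell markers, CD14 and ITGAM, rose and CD8A fell (4 and 1 adjusted over the list alone), and 2 of the 5 neural or liver markers, MBP and SERPINA1, rose (2 adjusted over the list alone).

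The response to 5-FU in cells with DAZAP2 siRNA was the difference between siDAZAP2_5-FU and siDAZAP2_DMSO. CDKN1A rose 11-fold, from 198.6 ± 28.4 to 2183 ± 207 CPM (log2 fold change 3.46, SE 0.10, adjusted p = 4.97e-15), and MDM2 rose 5.88-fold, from 212.7 ± 11.7 to 1252 ± 60.5 CPM (2.56, SE 0.09). TP53I3 rose 15-fold (3.91, SE 0.11), TP53INP1 8.36-fold (3.06, SE 0.11), the serpin SERPINB5 8.99-fold (3.17, SE 0.08) and FAS by 2.74. CEACAM1 rose 64.9-fold (6.02, SE 0.23). SORCS2 (5.26), SYT8 (5.05), HRNR (4.90), FLG (4.74), PVRL4 (4.36) and DRAXIN (4.35) also rose. PLK1 fell 4.14-fold, from 268 ± 6 to 64.8 ± 2.2 CPM (−2.05, SE 0.08, adjusted p = 1.32e-13). PCK2 (−2.69, SE 0.39), PIF1 (−2.54), RPL22L1 (−2.46), the glycine transporter SLC6A9 (−1.96), RAB26 (−1.95), CHAC1 (−1.90) and ASNS (−1.89, SE 0.30) also fell. HIPK2 fell by 0.31 (SE 0.09, adjusted p = 0.00583). SIAH1 was at −0.20 (adjusted p = 0.216). In all, 8080 of 16115 genes changed, 4104 higher and 3976 lower, and 1449 changed at least 2-fold.

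Gene groups in cells with DAZAP2 siRNA were counted in the same lists. Of 98 p53 targets, 92 rose and 3 fell (93 and 3 adjusted over the list alone), with a median of 1.30 and camera adjusted p = 8.93e-37 (adjusted p = 0.0111 with an estimated correlation). The targets that fell were KITLG, STEAP3 and WRAP53, singled out after their values were seen. By function, 13 of 13 targets of cell cycle arrest, 17 of 17 of apoptosis, 19 of 21 of repair and metabolism, 38 of 40 other targets and 7 of 9 feedback targets rose (13, 17, 19, 39 and 7 adjusted over the list alone). Of 34 mitotic genes 33 fell (33 adjusted over the list alone), with AURKA at −1.53, CDC20 at −1.64 and a median of −0.80, and of 36 replication genes 25 fell and 5 rose (25 and 5 adjusted over the list alone), with MCM6 at −1.20. Their camera adjusted p was 2.81e-15 and 2.37e-05, and with an estimated correlation the adjusted p was 0.203 and 0.325. Of 17 NF-κB genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), including IL8 (2.44) and BIRC3 (2.15), with adjusted p = 0.000338, and 0.0341 with an estimated correlation. Of 25 growth factor genes 18 rose and 1 fell (18 and 1 adjusted over the list alone), including HBEGF (2.23) and AREG (1.71), and of 21 mesenchymal and matrix genes 13 rose and 2 fell (13 and 2 adjusted over the list alone), including SNAI2 (4.06) and CYR61 (2.72). Those sets had camera adjusted p = 4.42e-07 and 0.000184, and adjusted p = 0.203 and 0.206 with an estimated correlation.

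Further lists in cells with DAZAP2 siRNA moved as follows. Of 26 ribosome biogenesis genes 18 fell and 1 rose (18 and 1 adjusted over the list alone), and of 30 ribosomal protein genes 15 fell and 1 rose (15 and 1 adjusted over the list alone), including RPL10A (log2 fold change −1.70). Of 22 cholesterol genes 13 fell and 2 rose (15 and 2 adjusted over the list alone). Their camera adjusted p was 7.27e-05, 0.000337 and 0.00217, and with an estimated correlation the adjusted p was 0.311, 0.485 and 0.367. Of 24 integrated stress genes 15 fell and 2 rose (15 and 2 adjusted over the list alone), with camera adjusted p = 0.0111 and adjusted p = 0.601 with an estimated correlation. Of 30 RNA processing genes 20 fell and 2 rose, and of 13 heat shock genes 11 fell and 1 rose (20 and 2, and 11 and 1, adjusted over the list alone). Of 18 epithelial genes 11 rose and 1, CLDN7, fell, and of 27 autophagy genes 16 rose and 1, BECN1, fell (11 and 1, and 16 and 1, adjusted over the list alone). These 4 sets had camera adjusted p = 1.25e-05, 0.00188, 0.00073 and 0.00367, and adjusted p = 0.311 with an estimated correlation. Of 30 interferon-induced genes 13 rose and 4 fell (13 and 4 adjusted over the list alone), with camera adjusted p = 0.0248 and adjusted p = 0.226 with an estimated correlation. Of 19 genes for HIPK2 and partners of it or DAZAP2, 4 rose and 8 fell (4 and 8 adjusted over the list alone), and the set did not pass (camera adjusted p = 0.138). The Wnt pathway inhibitor DKK1 rose by 1.75, and the pathway target AXIN2 fell by 1.16. DKK1 carried TGTACGT in its 3′ UTR, but both groups compared here had the same siRNA, and TGTACGT had z of −0.113.

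**Figure D4:**
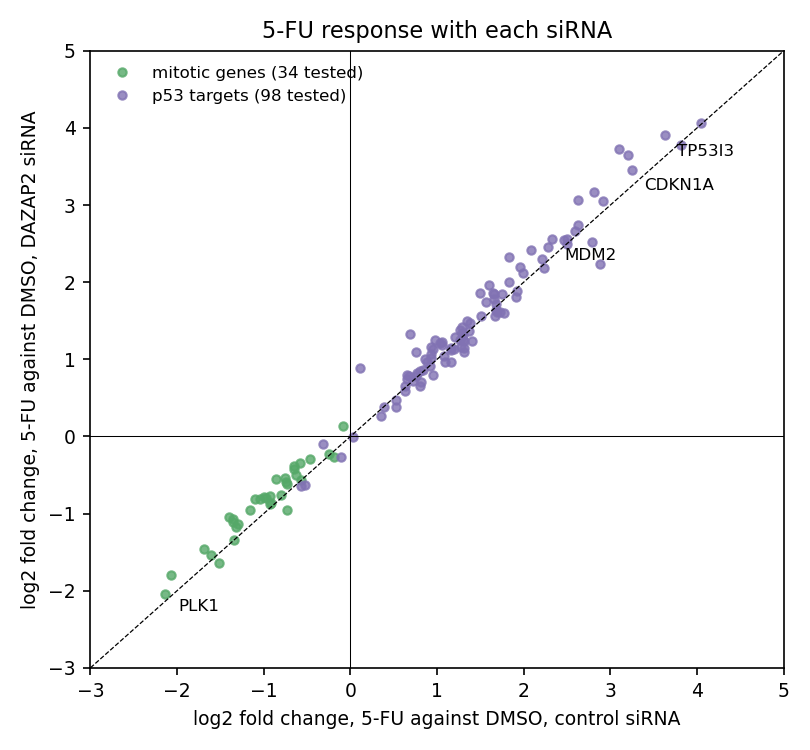
Log2 fold change with 5-FU in cells with control siRNA (x axis) and with DAZAP2 siRNA (y axis) for 98 p53 targets and 34 genes of G2 and mitosis (points), with a dashed line of equality. CDKN1A lies at 3.25 and 3.46, MDM2 at 2.33 and 2.56, TP53I3 at 3.63 and 3.91, and PLK1 at −2.13 and −2.05.

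Whether the response to 5-FU differed between the siRNAs was tested directly as an interaction. LAMA3, a laminin chain, was the 1 gene past the threshold (difference of log2 fold changes 0.81, SE 0.11, 1.75-fold, adjusted p = 0.00845). Its level was 21 ± 1.8 CPM in siCTRL_DMSO, 11.2 ± 0.25 in siDAZAP2_DMSO, 152 ± 2.5 in siCTRL_5-FU and 142 ± 7.6 in siDAZAP2_5-FU. The adjusted p of LAMA3 was 0.0726 without siDAZAP2_DMSO replicate 3, 0.0568 without siCTRL_5-FU replicate 1 and 0.0626 without siCTRL_5-FU replicate 3. In each of these, and without both DMSO libraries numbered 3, edgeR called 0 genes, with 693, 523, 835 and 689 genes at an unadjusted p under 0.05. It called 2 genes without siCTRL_DMSO replicate 1. Over all 12 libraries edgeR had 597 genes and DESeq2 544 at an unadjusted p under 0.05, and DESeq2 called 3 genes, CPA4, CYP4F3 and LAMA3. CYP4F3 was singled out after its value was seen. The difference was 0.08 for DAZAP2 (adjusted p = 0.995), 0.10 for HIPK2 (adjusted p = 0.984) and 0.19 for SIAH1. It was −0.0093, −0.16 and −0.23 for DAZAP2 without siCTRL_DMSO replicate 2, siDAZAP2_DMSO replicate 3 and siDAZAP2_5-FU replicate 3. It was −0.0047 for HIPK2 without siDAZAP2_DMSO replicate 2.

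As sets, genes of G2 and mitosis fell less with 5-FU in cells with DAZAP2 siRNA: the median difference of log2 fold changes was 0.17 over 34 genes (camera adjusted p = 7.49e-05, but adjusted p = 0.699 with an estimated correlation). The kinesin KIF20A was at 0.29 and the topoisomerase TOP2A at 0.30, neither past the threshold (adjusted p = 0.984). This set stayed past the threshold without each of the 12 libraries, with a highest adjusted p of 0.00675. The 98 p53 targets had a median difference of 0.053 (camera adjusted p = 0.014, but adjusted p = 0.699 with an estimated correlation). TP53INP1 was at 0.44, PMAIP1 at 0.37 and CCNG2 at 0.63, each with adjusted p = 0.984. The camera adjusted p of the p53 targets was 0.0554 without siCTRL_DMSO replicate 2, 0.0648 without siCTRL_DMSO replicate 3, 0.189 without siDAZAP2_DMSO replicate 3, 0.161 without siCTRL_5-FU replicate 3 and 0.204 without siDAZAP2_5-FU replicate 2. Across all 16115 genes the responses with either siRNA had Pearson's r of 0.924 and Spearman's rho of 0.887, with a slope of 0.975 and a jackknife SE of r of 0.0205. Both responses called 6384 genes, 3275 higher in both, 3108 lower in both and 1, ARRDC3, in opposite directions, where independent lists would share 981 higher and 907 lower. When genes with low counts were kept, r was 0.541.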

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

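Of the tests used here, the counts without both DMSO libraries numbered 3 were chosen only after the result was seen. A difference between the responses to 5-FU with the 2 siRNAs, tested as an interaction, singled out 1 gene and 8 gene lists. LAMA3 differed by 0.81 (0.8115) on the log2 scale (adjusted p = 0.00845), and its 3 libraries with DAZAP2 siRNA in DMSO lay below the 3 with control siRNA. Of 100 splits of the libraries drawn from 200 possible, 9 called at least 1 gene, the real one included. The others of these 9 all keep the 3 siCTRL_DMSO libraries together, so they carry the siRNA effect in DMSO and do not measure chance. The highest of them, with 2450 genes, exchanges the siRNA labels within 1 treatment and shows the siRNA effect itself, a structure of these samples. The splits therefore leave open whether chance can be excluded for the 1 gene called.

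The lists whose log2 fold change with 5-FU was shifted upward under DAZAP2 siRNA were the p53 targets (median difference 0.05316, camera adjusted p = 0.014), their apoptosis genes (0.1145, adjusted p = 0.00331), their feedback genes (0.1295, adjusted p = 0.0448), growth factor and MAPK genes (0.09973, adjusted p = 0.00331) and genes of G2 and mitosis, which fell less (0.1693, adjusted p = 7.49e-05), each with adjusted p = 0.699 with an estimated correlation. Those shifted downward, with a larger fall of the median under DAZAP2 siRNA, were ribosome biogenesis (−0.1038, adjusted p = 0.0017), ribosomal proteins (−0.0574, adjusted p = 0.0448) and cholesterol synthesis (−0.132, adjusted p = 0.00391). With an estimated correlation these had adjusted p = 0.699, except the ribosomal proteins with 0.958. Genes spanning up to 8.91 kb had a median log2 fold change with 5-FU of 0.0713 with control siRNA and 0.0067 with DAZAP2 siRNA. For those from 91.7 kb it was −0.0346 and 0.0145. Whether gene span, spliced length or GC content accounts for the shifts of these lists was not tested. Over all genes edgeR called 0 members of these lists (LAMA3 is not among them). Adjusted over the list alone, 1 feedback gene and 1 growth factor gene passed. Among members with small p were TP53INP1 at 0.44, PMAIP1 at 0.37, UBTF at −0.21 and the phosphatase DUSP6 at 0.37, each with adjusted p = 0.984 over all genes.

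The mitotic list kept its call without each of the 12 libraries. The other lists lost theirs without single libraries, as follows. For the p53 targets these were siCTRL_DMSO replicates 2 (0.0554) and 3 (0.0648), siDAZAP2_DMSO replicate 3 (0.189), siCTRL_5-FU replicate 3 (0.161) and siDAZAP2_5-FU replicate 2 (0.204). The apoptosis genes lost it without siCTRL_DMSO replicate 3 (0.0648) and siDAZAP2_5-FU replicate 2 (0.0608), and ribosome biogenesis without siCTRL_DMSO replicate 3 (0.0648). The feedback genes lost it without siCTRL_DMSO replicates 2 (0.345) and 3 (0.0648), siDAZAP2_DMSO replicates 1 (0.0748) and 3 (0.242), siCTRL_5-FU replicates 1 (0.104) and 3 (0.0748), and siDAZAP2_5-FU replicates 2 (0.0839) and 3 (0.072). Growth factor genes lost it without siCTRL_DMSO replicate 3 (0.0686), siCTRL_5-FU replicate 1 (0.114) and siDAZAP2_5-FU replicate 2 (0.0839). Cholesterol genes lost it without siCTRL_DMSO replicate 3 (0.143) and siDAZAP2_DMSO replicate 2 (0.0985). Ribosomal proteins lost it without siCTRL_DMSO replicates 2 (0.078) and 3 (0.193), siDAZAP2_DMSO replicate 2 (0.9), siCTRL_5-FU replicate 2 (0.587), and siDAZAP2_5-FU replicates 1 (0.0608) and 3 (0.327).

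Mitotic genes were higher with DAZAP2 siRNA under 5-FU, with a median log2 fold change of 0.30 over 34 genes (camera adjusted p = 2.49e-14, adjusted p = 0.601 with an estimated correlation). Against seed sites of the control siRNA as the cause, without PRC1, the 1 member of 34 that carries the last 6 bases of the 7-mer TGTACGT, the median of the other 33 was 0.299 (camera adjusted p = 4.1e-13). Carriers of TACTTCG or ACTTCGT, further 7-mers associated with higher levels, were not removed. Spread between libraries was tested by the gap between the lowest siDAZAP2_5-FU mean and the highest siCTRL_5-FU mean of the list, which was 0.143, so all 3 libraries with DAZAP2 siRNA lay above all 3 with control siRNA. Each library number occurs once in every group and the set kept camera adjusted p = 3.19e-12 with the replicate number as a block. Open are indirect effects of either siRNA on other genes and a dependence of the cell cycle under 5-FU on DAZAP2. The 1 DAZAP2 siRNA treatment used, whose sequence is not given in the sources used here, cannot part these. In DMSO the list was also higher with DAZAP2 siRNA by camera (adjusted p = 0.000178, but adjusted p = 0.728 with an estimated correlation). The library means overlapped there, with 7.373 as the lowest in siDAZAP2_DMSO and 7.379 as the highest in siCTRL_DMSO. Whether the shift extends to DMSO is therefore less certain than the shift under 5-FU. FOXM1, a member of the list, fell in both treatments (log2 fold change −0.49 in DMSO and −0.57 under 5-FU). A candidate explanation is that fewer cells with DAZAP2 siRNA left the cycle under 5-FU. These libraries do not test it, and it would not cover a shift in DMSO.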

How the results depend on the processing

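Fits without both DMSO libraries numbered 3, genes without seed sites, and correlations without single libraries were tests chosen only after the result was seen. Of 155 single-gene results with a call 153 kept it and their direction under every alternative, as did 12 of 63 list results with a call. List members with a call were named only where it held without each library, so the 153 was partly fixed in advance. It does not describe called genes in general. Of 19 single-gene and 4 list results without a call, 14 and 2 kept direction and stayed without one. Of 5 counts 2 held, those of the 5-FU responses. Of 651 list alternatives 551 left the call or its absence as it was, 96 lost it, 1 gained it and 3 turned direction, and an estimated correlation lost it for 51 of the 63. DESeq2's size factors lost 2 calls of the interaction, p53 feedback (0.05044) and ribosomal proteins (0.05139). DESeq2 called 1429 genes for DAZAP2 siRNA in DMSO and 3 for the interaction. Fitting only the groups compared gave 481 genes in DMSO and 1067 under 5-FU. Without both DMSO libraries numbered 3 there were 226 in DMSO, 223 of them among the 944, and edgeR called 0 in the interaction (689 unadjusted). Over genes without seed sites, fewer being tested, 676 and 501 changed. With no filter, r was 0.0857 between siRNA effects and 0.5414 between 5-FU responses. For these the cause was not tested.

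Without single libraries, counts ranged from 426 to 1342 (DMSO), 269 to 530 (5-FU) and 0 to 2 (interaction), and r from 0.4093 to 0.5014 and 0.894 to 0.9184. Fewer samples were fitted there. The adjusted p of the p53 targets ranged from 0.3799 to 0.9956 in DMSO, 0.01093 to 0.1704 under 5-FU (0.8863 with an estimated correlation) and 0.0005393 to 0.204 for the interaction (0.6991). Log2 values that changed sign ranged from −0.23859 to 0.0028733 (SIAH1, DMSO), −0.060731 to 0.16648 (SIAH1, 5-FU), −0.44756 to 0.20625 (DAZAP2, drug with DAZAP2 siRNA), and −0.22726 to 0.42513 (DAZAP2) and −0.0047319 to 0.15283 (HIPK2) for the interaction. For these too the cause was not tested.

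With the replicate block, 1347 and 1000 genes changed with DAZAP2 siRNA in DMSO and 5-FU, 8023 and 8564 with 5-FU under control and DAZAP2 siRNA, and 1 in the interaction. The block changed no call among the 67 list results and 174 single-gene results followed here. Over all genes, 928 of the 944 called in DMSO and 693 of the 710 called under 5-FU were called with the block too. Same-numbered libraries were not paired for DAZAP2 siRNA in DMSO (correlations 0.0622, −0.0519, 0.212) or 5-FU with control siRNA (0.0888, −0.0816, 0.175). Depth limits genes near the floor of 3 counts, 0.0628 to 0.0806 CPM.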

Other observations

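Tests of integrated stress genes against depth and a shared day were chosen only after the result was seen, as were counts over genes without seed sites. Genes of the cornified envelope, which are expressed late in epidermal differentiation, were gathered in a list after FLG and HRNR had been seen to rise with 5-FU. With control siRNA 11 of 15 tested members rose (11 adjusted over the list alone), with a median log2 fold change of 0.82 and camera adjusted p = 0.0001888. With DAZAP2 siRNA 9 rose (10 adjusted over the list alone), with a median of 0.65 and camera adjusted p = 0.0002877. With an estimated correlation the adjusted p was 0.0252 and 0.0298. The protease KLK5, the envelope proteins LCE1C and IVL and the crosslinking enzyme TGM1 were among them, chosen after their values were seen. Reads of LCE1C can be shared with other LCE genes.

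The fall of TAGLN, MYL9 and CYR61 with DAZAP2 siRNA led to 3 lists of actin and matrix regulators. Of 27 targets of SRF and its cofactors MRTF, 4 fell in DMSO (TPM4, FLNA, VCL and LIMA1) and 4 under 5-FU (VCL, MYH9, FLNA and TPM4), with camera adjusted p = 0.04099 and 0.00817 (adjusted p = 0.711 and 0.742 with an estimated correlation). Adjusted over the list alone, 1 rose and 7 fell in DMSO, and 1 rose and 6 fell under 5-FU. Of 20 targets of YAP and TEAD, 3 fell in DMSO (F3, PTPN14 and CRIM1) and 1 under 5-FU (F3), with 0.04099 and 0.0314, and adjusted over the list alone 4 fell in DMSO and 1 under 5-FU. That list too had adjusted p = 0.711 and 0.742 with an estimated correlation. Of 21 TGF-beta and SMAD targets 1, SMURF2, fell in DMSO (3 adjusted over the list alone), and the set did not pass in DMSO (0.1256) or under 5-FU (0.1483). These genes were chosen after their values were seen. The cause of their fall was not tested. Long genes can lose transcripts when DNA is damaged. The partial Spearman correlation of gene span with the response to 5-FU was computed over 15333 genes, with spliced length and GC content held. It was −0.0354 with control siRNA and −0.0141 with DAZAP2 siRNA, less negative than the −0.1 set for such a loss. For the effect of DAZAP2 siRNA in DMSO, Spearman's correlation with gene span was −0.193, and −0.0364 with both held. Genes spanning up to 8.91 kb had a median log2 fold change of 0.0652 there, and those from 91.7 kb had −0.0642. Under 5-FU the correlation for DAZAP2 siRNA was −0.00998, and 0.0137 with both held. Whether this trend accounts for shifts of gene lists was not tested.

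Seed sites in 3′ UTRs went with the effects of DAZAP2 siRNA: the 7-mer CCGCATT had z of −11.2 in DMSO and −8.93 under 5-FU, with lowest permuted values of −5.14 and −4.85, and TGTACGT had z of 11.4 and 12, with highest permuted values of 4.648 and 4.567. Other 7-mers also lay above these highest permuted values, among them TACTTCG (z of 6.74 and 6.49) and ACTTCGT (5.88 and 5.97). TCCGCAT (−5.59 and −4.88) also lay below the lowest permuted values. In DMSO CCGCATT stood in 50 of 440 lower genes (11.4%) against 218 of 13137 unchanged genes (1.66%, Fisher's exact p = 2.43e-24), and TGTACGT in 61 of 457 higher genes (13.3%) against 374 (2.85%, Fisher's exact p = 7.57e-22). CCGCATT and TGTACGT were picked as the extremes over these same fold changes, so the Fisher's exact p do not allow for that choice and add no separate evidence. CCGCATT also lies in the coding sequence of DAZAP2 (chromosome 12, 51240926 to 51240932, GRCh38, in 5 of 8 transcripts), as 20.49% of tested 7-mers lie somewhere in a DAZAP2 transcript, and in the comparisons of 5-FU with DMSO both had z between −0.113 and 2.28. Direct repression by the DAZAP2 siRNA, and relief from the control siRNA, may therefore account for part of the changed genes, while 676 and 501 genes still changed among 12368 that held neither CCGCATT nor TGTACGT nor the last 6 bases of either. Carriers of TCCGCAT, TACTTCG or ACTTCGT were not removed as such from these 12368. Of 21 mesenchymal and matrix genes, 3 carry CCGCATT or its last 6 bases in the annotated 3′ UTR searched. Without these 3, the median of the other 18 was −0.329 in DMSO and −0.276 under 5-FU. Such sites in the 3′ UTRs searched therefore do not account for the shift of the other 18. The whole list had camera adjusted p = 0.728 and 0.601 with an estimated correlation. Carriers of TCCGCAT were not removed as such, and indirect effects of either siRNA remain open.

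Integrated stress genes stood higher in the DMSO libraries numbered 3, by 0.438 and 0.477 in mean log2 CPM over the next library of siCTRL_DMSO and siDAZAP2_DMSO. Depth does not account for both: siCTRL_DMSO replicate 3 was the shallowest of its group, but siDAZAP2_DMSO replicate 3 was at place 2 of 3 by depth, counted from the shallowest. A culture day that acted alike in all libraries numbered 3 would raise those with 5-FU too. There, siCTRL_5-FU replicate 3 stood at −0.026 and siDAZAP2_5-FU replicate 3 at −0.049 against the highest of the others. Over all tested genes, deviations from the group means correlated between libraries numbered 3. The values were 0.212 and 0.378 for DAZAP2 siRNA in DMSO and under 5-FU. For 5-FU with control and DAZAP2 siRNA they were 0.175 and 0.241. A shared day is therefore not excluded. Open are a day on which 5-FU also removed the difference, and a difference of medium or density in the DMSO cultures, for which the labels give no record. No biological explanation was tested.

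Other splits of the 6 libraries were compared for each pairwise count. Of 10 splits, 1, the real one, called as many genes in each of the 4 comparisons (944, 710, 7527 and 8080). The 9 others called 0 genes each with edgeR, with at most 2000, 1230, 1107 and 905 genes at an unadjusted p under 0.05. With 10 splits no share under 0.1 can be had. Under pairing by number, the 3 other splits that part all pairs also called 0.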
